A study of Micropterus salmoides with 8 samples.

How the data were processed

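Testis RNA of largemouth bass (Micropterus salmoides, a freshwater predatory fish) was measured on 8 single-channel Agilent arrays, 4 from control fish and 4 from fish fed toxaphene, a mixture of chlorinated camphenes once used as an insecticide. The groups were taken from the sample type in the labels, and the series' design text calls the samples of a group biological replicates. Replicate numbers follow the order of deposit, since the labels give none, and they coincide with the slide: arrays with the same number lay on the same slide. Total RNA was labelled with Cy3 per the labels' protocols. Dose and duration of feeding are not given in the sources used here, and the liver arrays that the design text mentions were not analysed here.

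The deposited scanner tables hold intensity values written by Agilent Feature Extraction 10.1.1.1, per the file headers. The processed intensity of a spot had already been corrected for local background and for spatial and multiplicative trends, and dim spots carried a substitute value derived from the background, per the file headers. No scaling between arrays had been applied to these intensities. The authors also deposited a value table of the same arrays, in log2 units according to a comparison with the scanner values: the slope of each column on the log2 processed signal of its own array lay between 0.971 and 1.03. Each of the 8 columns correlated best with its own array. Column medians were 8.782 in controls 1, 2 and 3, 8.779 in control 4, and 8.782, 8.795, 8.785 and 8.784 in toxaphene 1 to 4. Sorted values of the columns nearly coincided, as after quantile normalization, and between 249 and 344 probes per column lay at a common floor of 2.1. How that floor and scaling were made is not given in the sources used here, and direction was taken from the scanner values.

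Each array carried 15744 spots, of which 536 were control spots and were left out, leaving 15208 probes. Spots that the software called non-uniform or population outliers were left out (0 to 14 per array), and saturated spots (0 to 2 per array) were kept. Each remaining spot was its own probe, so no spots were averaged. The log2 processed signal minus the array's 75th percentile was the value analysed. A probe was tested when it was well above background on at least 4 of the 8 arrays, whichever group these belonged to, which kept 14101 probes and left 1107 untested. Group differences, toxaphene minus control, were fitted without covariates with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p values were adjusted by the Benjamini-Hochberg method over all tested probes, with a threshold of 0.05. The number of arrays limits the precision of every value.

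For a probe not well above background on any array of a group, the difference in the main fit is given as a bound. The mean of the brighter group was set against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background on that array. The p values of such a probe, and its differences under other settings, come from its own signals and not from the bound. Single values were compared with exact permutation tests on all splits of 4 against 4, for which the smallest possible p is 0.0286. Tests between groups were two-sided, and the test against random sets of probes counted the upper tail.

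The fit was tested on simulated data for toxaphene against control with 14101 probes, 50 of them changed at each of 4 sizes. It recovered 38% of probes changed by a log2 size of 1, 88% at 2, 90% at 3 and 98% at 4, with 7 false calls among 164. The simulated noise was normal and independent between probes, and followed the variance distribution that limma estimated. It was of equal size on all arrays, with no slide or scan day effect and no deviant array. The shares therefore test the fit under these settings and do not measure its performance on the real arrays.

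The groups, the test, the alternatives and the rule for naming probes were chosen before the data were examined. That rule took the 10 largest rises and the 10 largest falls past the threshold, filled a direction with fewer than 10 by the smallest unadjusted p, took the 3 members of each of 24 gene lists with the smallest p, and always took a set of steroid, hormone receptor and liver protein genes. It also required a gene name. The arrays give no description for any probe, 29 probe names are sequence accessions, 0 of these appear in the gene table used for names, and the 24 lists matched 0 probes. The files do not pair the probe identifiers with genes, so only 2 identifiers that rose and 2 that fell are printed, chosen by size of change, and the list tests (camera, and fry as an alternative) could not be run.

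Slide and scan day were treated as batches. The 8 arrays lay on 4 slides, each with 1 control and 1 toxaphene array, and were scanned on 2 days, 2 slides on each. Alternatives were quantile normalization, normexp background correction with an offset of 50 alone and with quantile normalization, scaling by the median, the deposited value table, 3 other filters on dim probes, slide as a fixed and as a random block, a variance trend with robust estimation, array weights, other thresholds, and leaving out each array in turn. Scan day as a block, each scan day alone and the place of control 2 under other scalings were added after the data were seen.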

Results

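Transcript levels in testis were measured in 4 control and 4 toxaphene-fed male largemouth bass, with 1 array per sample. The series concerns the effects of dietary toxaphene on the liver and gonad. Between 13109 probes (toxaphene 4) and 14268 probes (control 2) of 15208 were well above background on an array, 12834 were so on all 8 arrays and 521 on none. The 75th percentile of the signal lay between 1874 (control 4) and 2878 (toxaphene 3), and the slope of the spike-in response between 0.987 and 1.03. Probe identifiers are given as the arrays give them, since the files do not pair them with genes.

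In the testis of toxaphene-fed fish 45 probes were higher and 83 lower than in controls, 128 of 14101 tested (0.908%), by limma with Benjamini-Hochberg adjusted p under 0.05. The median log2 difference was 1.34 among the higher probes (range 0.85 to 3.51) and -1.50 among the lower ones (range -4.41 to -0.997). Among probes past the threshold the largest rises were about 11.4-fold and 8.08-fold and the largest fall 21.2-fold. A much wider set lay near the threshold: 4189 probes had an unadjusted p under 0.05 (1906 higher, 2283 lower) where 705 would be expected by chance, and 2427 passed an adjusted threshold of 0.10 (1252 higher, 1175 lower). The 4 toxaphene values did not overlap the 4 control values at 2140 probes, 15.2% of those tested against 2.86% by chance. The share of unchanged probes estimated by limma was 60.5%. The measured log2 difference was over 2 at 54 probes and under -2 at 33.

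The count of 128 depended on single arrays, on the scaling, on the filter, on the variance model and on blocks. It fell to 6 with slide as a fixed block and to 3 with scan day as a block, and rose to 519 with slide as a random block. It was 3995 (1955 higher, 2040 lower, all 128 among them) without control 2, 21 without toxaphene 1, 6 without control 4, 3 without toxaphene 2, 1 without toxaphene 3, and 0 without control 1, control 3 or toxaphene 4, where limma still gave between 2898 and 5693 probes with an unadjusted p under 0.05 in each of the 8 fits. The balance of directions moved from 45 higher of 128 to 144 higher of 278 with quantile normalization and 141 of 267 in the deposited value table. It was 452 of 716 with scaling by the median and 704 of 1203 with normexp and quantile normalization together. With normexp alone 0 probes passed. The median difference over all tested probes was -0.12 on the log2 scale, a shift that the printed differences contain, and it was -0.06 with quantile normalization and -0.34 with normexp background correction.

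Past the threshold, the largest rise was at UF_Msa_CF_124056 (target contig14431, probe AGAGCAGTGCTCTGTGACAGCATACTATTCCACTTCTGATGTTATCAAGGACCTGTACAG), 11.4-fold higher in toxaphene-fed fish. Its log2 level relative to the 75th percentile was -4.21 ± 1.16 in controls and -0.70 ± 0.997 in toxaphene-fed fish (SD, n = 4 each), a difference of 3.51 with a standard error of 0.625 (limma, adjusted p = 0.0464). UF_Msa_AF_109715 (target contig13327, probe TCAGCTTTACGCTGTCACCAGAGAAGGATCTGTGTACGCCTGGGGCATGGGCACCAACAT) rose 8.08-fold, from -2.19 ± 0.671 to 0.82 ± 0.124. That difference of 3.02 had a standard error of 0.307 and the smallest adjusted p of the comparison, 0.0216 (limma), and the toxaphene-fed fish were close to each other.

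The largest fall past the threshold was at UF_Msa_AD_200128 (target LMB_Add_117, probe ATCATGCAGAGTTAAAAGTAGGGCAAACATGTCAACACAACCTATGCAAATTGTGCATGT), 21.2-fold lower in toxaphene-fed fish, from -1.46 ± 1.22 to -5.86 ± 0.820 (SD, n = 4 each), a difference of -4.41 with a standard error of 0.602 (limma, adjusted p = 0.0332). The other probe of that target, whose target name carries the ending rc, differed by 0.09 (adjusted p = 0.868 with limma). Of 197 such pairs 44 overlap on opposite strands and 0 on the same strand. The other probe therefore need not measure the same transcript. UF_Msa_AD_200264 (target LMB_Add_92, probe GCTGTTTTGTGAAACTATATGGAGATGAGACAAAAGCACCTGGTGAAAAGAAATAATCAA) was well above background on all 4 control arrays and on 0 of the 4 toxaphene arrays, so its fall was at least 8.92-fold (limma, adjusted p = 0.0242).

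All 4 kept their direction in every fit in which they were tested. Leaving out an array could not turn it, since the control and toxaphene values of each probe did not overlap. Slide and scan day blocks left the differences unchanged. None of the 4 passed the adjusted threshold without control 1, control 3, toxaphene 3 or toxaphene 4. Without control 3 the adjusted p (limma) was 0.162 for UF_Msa_CF_124056, 0.14 for UF_Msa_AF_109715, 0.145 for UF_Msa_AD_200128 and 0.14 for UF_Msa_AD_200264. Without toxaphene 2 the call also ended for UF_Msa_CF_124056 (0.0637), UF_Msa_AF_109715 (0.0513) and UF_Msa_AD_200128 (0.0515), and without toxaphene 1 or control 4 for UF_Msa_CF_124056 (0.106 and 0.131). Normexp background correction ended all 4 calls, with log2 differences of 2.41, 2.50, -2.89 and -1.78 in the order of the probes above (limma, adjusted p 0.326, 0.161, 0.263 and 0.627). With normexp and quantile normalization together all 4 passed, at 2.42, 2.45, -2.25 and -1.07. For UF_Msa_AD_200264 the normexp sizes rest on toxaphene signals not well above background.

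**Figure D1:**
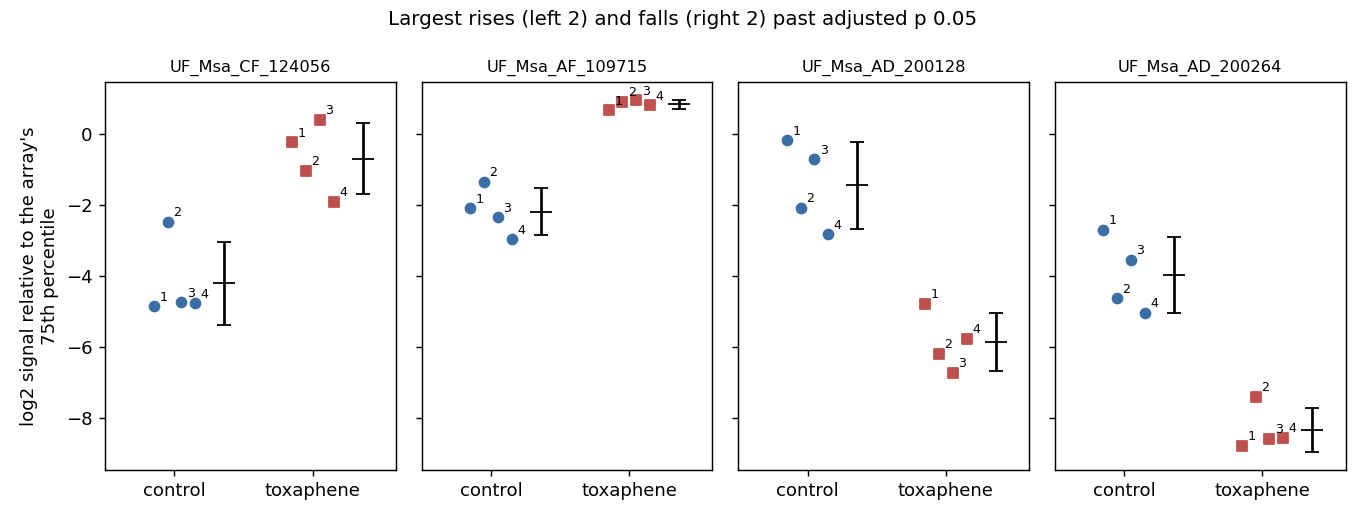
Log2 signal relative to the array's 75th percentile (vertical axis) of the 2 largest rises and the 2 largest falls past the threshold, with a point per array numbered by replicate and bars showing the mean and SD of 4 arrays. At UF_Msa_AF_109715 the controls lie at -2.19 ± 0.671 and the toxaphene-fed fish at 0.82 ± 0.124, and at UF_Msa_CF_124056 control 2 lies above the other controls.

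Detection itself differed at few probes: 7 were well above background on all 4 control arrays and on 0 toxaphene arrays, and 0 the other way round. Of these 7, 3 passed the limma threshold. Their falls were at least 1.15-fold to at least 9.29-fold, with a median of at least 1.71-fold.

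The 33 probes with a measured log2 difference under -2 included a set that varied together among the control fish, found after the values were seen. The log2 profile of the 3 largest falls past the threshold over the 4 controls was followed (slope 0.5 to 1.5, residual under 0.25) by 10 of the other 30. Random sets of probes of similar spread among the controls held 1.14 such probes on average, which is given without a test because the pattern was found on the same arrays. The mean log2 level of these 13 probes was -3.29 ± 1.01 in controls and -6.56 ± 0.665 in toxaphene-fed fish (SD, n = 4 each), a difference that chose the set. Of the 13, 7 passed the limma threshold, among them the 3 of the profile, which were chosen from probes past it. Of the 13, 6 were well above background on all 8 arrays and 2 on 0 toxaphene arrays. The toxaphene level of the set therefore rests in part on signals not well above background, and its distance from the controls is uncertain. The level of the set was -2.15, -3.96, -2.76 and -4.29 in controls 1 to 4, and -5.99, -6.62, -7.47 and -6.16 in toxaphene 1 to 4. Of the 54 probes with a log2 difference over 2, 0 followed that profile, and random sets of similar spread held 2.29 on average.

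**Figure D2:**
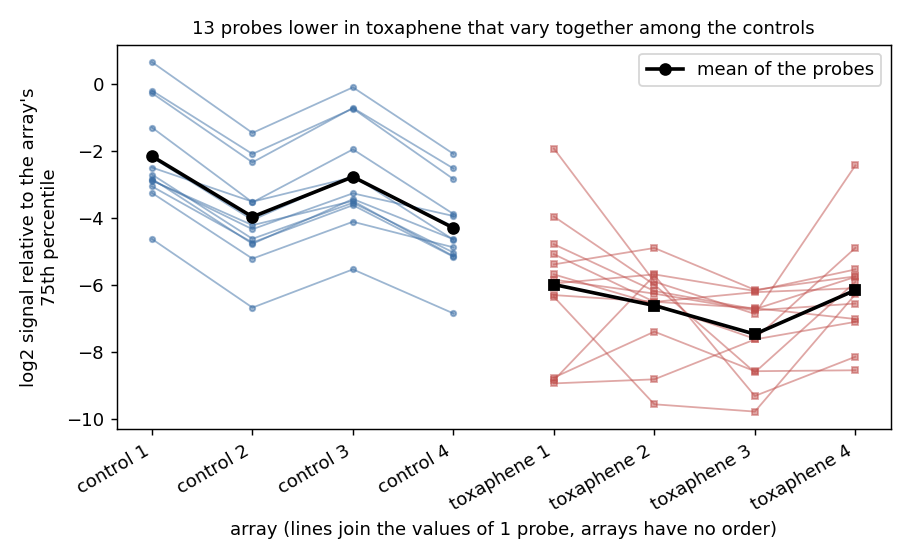
Log2 signal relative to the array's 75th percentile (vertical axis) on each of the 8 arrays (horizontal axis) for 13 probes lower in toxaphene-fed fish, with a thin line per probe and the mean in black. The mean lies between -4.29 and -2.15 in the controls and between -7.47 and -5.99 in the toxaphene-fed fish.

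Across all tested probes the first principal component held 43.5% of the variance and separated the groups (exact permutation p = 0.0286, the smallest possible). That test ignored the slides, and splits that keep 1 array of each slide on each side cannot give a share under 0.125. On this component control 2 lay beside the toxaphene arrays. Its score was 16.9, against -46.2, -49.9 and -58.9 for controls 1, 3 and 4 and 25.5, 36.4, 33.3 and 42.9 for toxaphene 1 to 4. On the second component, with 17.2% of the variance, control 2 lay apart from the toxaphene arrays. It scored 37.4 there, against 12.6, 6.61, -36.1 and -6.57 for toxaphene 1 to 4. Controls 1, 3 and 4 scored -36.6, -7.53 and 30.1. The mean correlation across probes, which are not independent replicates, was 0.961 between control 2 and the other controls and 0.976 between control 2 and the toxaphene arrays. Within the toxaphene arrays it was 0.979, among controls 1, 3 and 4 it was 0.978, and between these 3 controls and the toxaphene arrays 0.955. The median SD of a probe was 0.37 among the 4 controls, 0.27 without control 2 and 0.28 among toxaphene arrays.

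**Figure D3:**
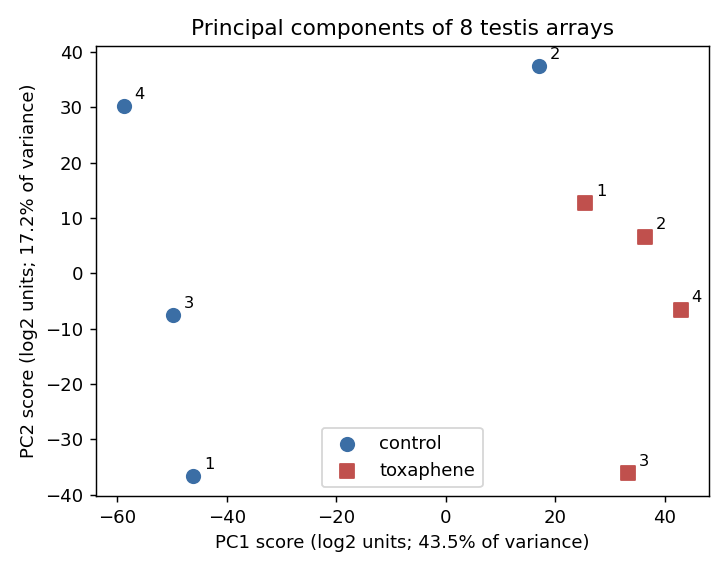
Scores of the 8 arrays on the first principal component (horizontal axis, 43.5% of the variance) and the second (vertical axis, 17.2%), in log2 units, numbered by replicate. Control 2 at 16.9 on the first axis lies nearer to the toxaphene arrays (25.5 to 42.9) than to the other controls (-58.9 to -46.2).

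At the 3995 probes past the limma threshold without control 2, the place of control 2 was expressed on a scale from 0, the mean of controls 1, 3 and 4, to 1, the toxaphene mean. Its median was 0.83 (0.831 with quantile normalization, 0.827 in the deposited value table, 0.837 with scaling by the median and 0.972 with normexp, each at the probes past the threshold there). With normexp the median log2 value of the control 2 array was -0.45, against -1.93 with the main scaling. In the main scaling the position of control 2 had a median of 0.871 at the 1955 higher probes and 0.774 at the 2040 lower ones. Control 2 lay over 0.75 at 2383 of these probes (59.7%) and under 0.25 at 333 (8.34%), of which 63 were among the higher and 270 among the lower probes. In fits that also left out a toxaphene array in turn, control 2 had median positions of 0.913 to 0.957 at the 189 to 237 probes past the threshold with a log2 difference over 2, against 0.902 to 1.06 for the left-out array. At the 34 to 42 probes with a log2 difference under -2 control 2 lay at 0.198 to 0.333, against 0.736 to 0.923.

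**Figure D4:**
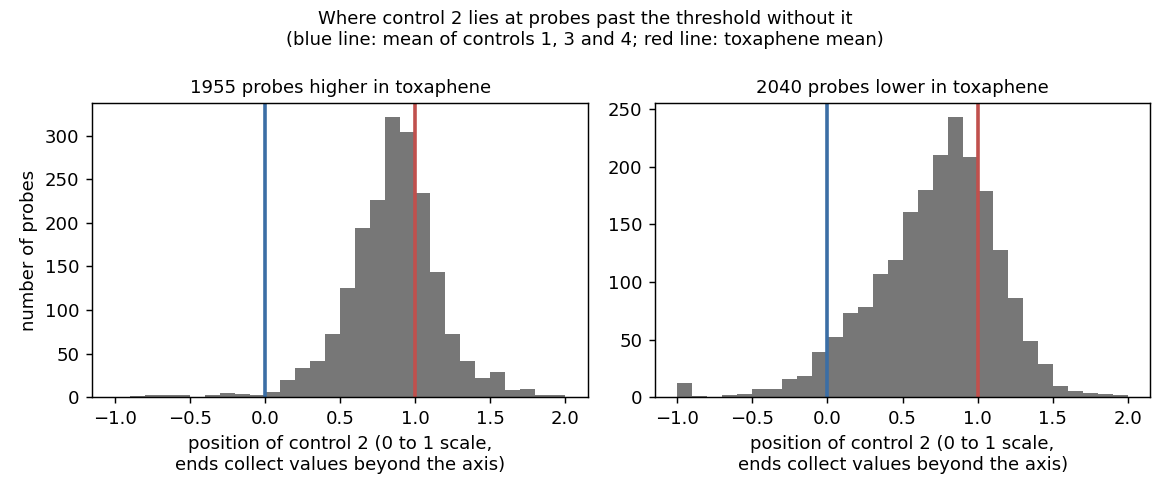
Number of probes (vertical axis) by the position of control 2 (horizontal axis, 0 for the mean of controls 1, 3 and 4 and 1 for the toxaphene mean), for 1955 probes higher (left) and 2040 lower (right) in toxaphene-fed fish in the fit without control 2. The medians are 0.871 and 0.774, and the lower probes have a longer tail toward 0.

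Differences between the groups were also taken within slides and scan days. At the 45 higher probes the median log2 difference was 1.33, 0.81, 1.49 and 1.67 on slides 1 to 4, and at the 83 lower probes -1.30, -1.05, -1.58 and -1.75. These probes were chosen on the same arrays, so their direction within slides follows in part from that choice. Of all tested probes 5116 had the same direction on all 4 slides (36.4% against 12.5% by chance). With slide as a fixed block 6 probes passed (4 higher, 2 lower) and with scan day as a block 3 passed (3 higher, 0 lower), while limma gave 3945 and 4040 probes with an unadjusted p under 0.05. UF_Msa_AF_109715 passed under both blocks (adjusted p 0.0402 and 0.0456 with limma). UF_Msa_AD_200128 passed with slide as a block (0.0402) and missed the threshold with scan day (0.0584). UF_Msa_CF_124056 (0.0768 and 0.0656) and UF_Msa_AD_200264 (0.0646 and 0.0519) missed it under both. On the first scan day alone, with 2 arrays per group including control 2, limma called 0 probes (405 with an unadjusted p under 0.05), and on the second day alone 1080 (758 higher, 322 lower). Of all tested probes 71.3% had the same sign on both days, and the differences of the separate days correlated across probes with r = 0.578. Between the 2 slides of the first day, slides 1 and 2, the differences correlated with r = 0.0239 only. For slides 3 and 4, of the second day, r was 0.637, and for the other pairs of slides it lay between 0.287 and 0.483.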

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

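The tests of control 2, of the unadjusted count and of the splits that keep the slides were chosen after the result was seen, and the comparison of the adjusted count with other splits was planned.

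Of 18 groups of 4 values examined, 3 held an array whose gap to its nearest neighbour passed the critical value of Dixon's test, which chance gives in about 1 of 20 groups. Control 2 stood apart from the other controls on the first principal component (gap 0.832 of the range) and at UF_Msa_CF_124056 (0.957), where it was brighter. Toxaphene 2 stood apart from the other toxaphene arrays at UF_Msa_AD_200264 (0.841), a probe not well above background on any toxaphene array.

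Control 2 lay with the toxaphene arrays at most probes that separated these from controls 1, 3 and 4. Poor hybridisation in the form of fewer detected probes is argued against by its 14268 probes well above background, the highest number of the 8 arrays. That count also depends on background noise, which was lowest on control 2. The SD of its negative controls was 2.232, against 2.555 to 4.138 on the other arrays, so other technical faults of control 2 stay open. An exchange with a toxaphene array needs a toxaphene array among the controls, and none was found: the median positions of the 4 toxaphene arrays, each at probes past the threshold without it and without control 2, were 0.873, 0.995, 0.905 and 1.04. A toxaphene-fed fish under a wrong label stays open. In the same 4 fits control 2 had medians of 0.804, 0.813, 0.831 and 0.848, each below the left-out array of the same fit. Control 2 had 6.15% to 12.6% of the probes under 0.25, where the left-out arrays had 1.78% to 5.53%. The probes with a log2 difference under -2 went the other way, with control 2 at 0.198 to 0.333 and the left-out arrays at 0.736 to 0.923, but these are 34 to 42 probes, some with a like profile among the controls, and the median at all lower probes was 0.774. A difference between fish within the control group stays open too, and no biological explanation was tested, since the labels describe the fish only by group.

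The split of the arrays into control and toxaphene gave 128 probes past the adjusted threshold, and the highest other split gave 1. For that count 1 of 35 splits gave as many, the smallest share that free splits can give. For probes with an unadjusted p under 0.05 the real split gave 4189. The highest other split, with control 2 and toxaphene 3 exchanged, gave 3520, and 1 of 35 splits gave as many. These shares argue against chance only if the slides are ignored, since each slide held 1 array per group. Only 8 splits keep 1 array of each slide on each side, which is too few for a share under 0.125. With the slides kept, chance therefore cannot be excluded by splits. Among these 8 the highest other counts were 0 and 2363, against 128 and 4189, and with slide as a fixed block they were 0 and 1860, against 6 and 3945.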

How the results depend on the processing

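Scan day as a block and each scan day alone were chosen after the result was seen. The count of 128 probes was within 1.5 times in no alternative. Among other scalings and corrections it was 278 with quantile normalization, 267 in the deposited value table, 716 with scaling by the median, 1203 with normexp and quantile normalization together, and 0 with normexp alone. Normexp alone left the median of control 2 at -0.45 and that of toxaphene 1 at -1.08, against -1.98 to -1.79 on the other 6 arrays (-2.10 to -1.93 on all 8 with the main scaling), so that probes of middle signal on these 2 arrays, 1 of each group, lay above the rest, and its unadjusted count was 1484. Among filters the count was 63 with none, 569 with probes well above background on all 8 arrays and 1258 in the upper part by mean signal. It was 1113 with a variance trend and robust estimation, and 4080 with array weights, where control 2 received 0.263 and the other arrays 0.882 to 1.73. Slide as a random block gave 519 (correlation within slide 0.061), slide as a fixed block 6 and scan day as a block 3. The first scan day alone gave 0 (unadjusted 405) and the second 1080, with 2 arrays per group. At an adjusted threshold of 0.10 the count was 2427, and at an unadjusted one of 0.05 it was 4189. Leaving out an array gave 0 to 3995 for the adjusted count and 2898 to 5693 for the unadjusted one. The cause of these moves was not tested. The 4 named probes kept their sign in all settings, which their choice by size on these same arrays fixed in large part. They missed the threshold in 11 of 20 (UF_Msa_CF_124056, log2 2.41 to 4.09), 6 of 21 (UF_Msa_AF_109715, 2.45 to 3.30), 7 of 20 (UF_Msa_AD_200128, -4.87 to -2.25) and 7 of 19 (UF_Msa_AD_200264, -4.71 to -1.07). The list tests, their alternatives and the averaging of probes of a gene were not run, since no probe has a gene name. Signal over background limits the size of falls to bounds where toxaphene arrays did not measure a probe. This holds for UF_Msa_AD_200264, whose range above rests on toxaphene signals not well above background.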

Other observations

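The tests of the large falls and of the probe pairs were chosen after the result was seen.

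Of the 33 probes with a log2 difference under -2, 14 belonged to the targets whose names begin with LMB_Add or LMB_S454.sd, which make up 716 of the 14101 tested probes. Of the 54 probes with a log2 difference over 2, 1 belonged to them. These names were picked out because the falls were seen among them, so the counts are given without a test.

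The 13 large falls with a like profile among the controls may share a source, such as a cell type or a common regulator, and should then also vary together among the toxaphene arrays, which did not choose them by their pattern. For the 6 of the 13 probes well above background on all 8 arrays the mean correlation between probes over the 4 toxaphene arrays was 0.451, against 0.0624 expected in random sets of similar spread there (permutation p = 0.0326), and 0.943 over the controls, by which they were chosen. The random sets were matched by spread and not by signal level, so the comparison cannot tell a shared source from shifts common to dim probes. Shifts of the 6 probes among the toxaphene arrays were also unequal. Their residuals from the shared profile were 0.164 to 1.56 (median 0.485) there, against 0.134 to 0.434 (median 0.21) among the controls. These 6 probes on 4 arrays therefore leave a shared source open. Shared probe sequence is argued against, since 2.56% of the 78 pairs among the 13 probes share a word of 15 bases on either strand. Cell types were not tested, because the probes have no gene names.

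Probes that come in pairs for a target, with names that differ by the ending rc, gave differences that were at most weakly related. Of 394 such probes in 197 pairs, 44 pairs overlap on opposite strands and 0 on the same strand. In the 145 pairs with both probes tested the differences correlated across pairs with r = 0.0991. Of the 7 probes of that series past the threshold, 3 had a tested partner, and 0 partners passed. Since 0.908% of all tested probes passed, 3 partners are too few for a conclusion. Pairs of probes with identical sequence gave a measure of the technical limit: over 48 such pairs r was 0.950, and the SD of the difference between them was 0.177, against 0.606 for the differences over all tested probes.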
